A study of Homo sapiens with 10 samples.

How the data were processed

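RNA from 5 lines of HCT116, a human colorectal carcinoma line, was hybridised to Affymetrix arrays. Per the labels' protocols, cells were untreated and kept at 37 °C in 5% CO2, total RNA was extracted with Trizol, and biotinylated cRNA was made by the manufacturer's kit protocol. Per the labels, 1 line is wild type (WT), ORC1B14 and ORC1BP32 are ORC1 mutants and ORC2B2 and ORC2BP8 are ORC2 mutants, each with arrays titled biological replicate 1 and 2. The labels do not say whether replicates came from separate cultures or extractions, so p-values measure only the spread between these samples, which may be technical.

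The authors deposited 1 log2 expression value per probe set and array, in 1 table of 53617 probe sets and 10 arrays. The submitters' processing notes name Affymetrix Expression Console, with no version. The log base is written in no label. The values, with a minimum of 1.45 and array medians near 4, were read as log2, and fold changes rest on that reading. How the arrays were normalized, the annotation and the genome build are not given in the sources used here. Array medians were 3.96 (WT), 3.95 (ORC1B14), 3.94 (ORC1BP32), 3.94 (ORC2B2) and 3.95 (ORC2BP8) for replicate 1, and 3.87, 3.89, 3.89, 3.88 and 3.87 in the same order for replicate 2. The values were taken as normalized between arrays, and used without further scaling. No 2 arrays held identical values (0 pairs), and correlations were 0.979 to 0.984 between arrays of a line and 0.968 to 0.989 between arrays of different lines. Arrays give no read depth; their number limits the precision.

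Probe sets were named through a table that pairs them with the platform's annotation. Exactly 1 symbol was found for 16098 probe sets and several for 0, and 37519 were unnamed here, which does not mean that they lack a gene. All 16098 matched the RefSeq gene table (GRCh38.p14) by gene ID, with 0 symbols updated, giving 14884 genes. That table was used only for names, gene length and the order of genes on chromosomes, and no coordinates are printed since no build is named for the array. A probe set was kept when it lay at or above the array median of all probe sets on at least 2 arrays, which left 11554 named probe sets and 10797 genes. For the 421 genes with more than 1 such probe set the one with the highest mean stood for the gene. ORC1 to ORC6 were always to be reported, but 0 of these 6 were named, so they are not analysed here.

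Differences were tested in R 4.3.3 with limma 3.58.1, with lmFit on 5 line means and eBayes with an intensity trend, so that all 10 arrays shared 1 estimate of the spread (5 residual and 5.83 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg over the genes tested, two-sided, with a threshold of 0.05. Each mutant line was compared with WT, genes called in both lines of a mutated gene and in all 4 lines were counted, and the ORC1 lines were compared with the ORC2 lines and the lines of each mutated gene with each other. Overlaps of comparisons that share the WT arrays were set beside independent lists (product of both counts over the genes tested) and beside 100 simulated data sets of unchanged lines, later also at an unadjusted p under 0.05. Simulated values were drawn for each gene on its own, with no correlation between genes and no effect of the replicate number. Their covariance was also computed with no WT array in common, each line minus the WT array of a different replicate number.

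Of 26 gene lists, with 641 genes, 375 genes were named on the array. They were origin recognition complex, origin licensing and MCM helicase, replication initiation and fork, G1/S cyclins with E2F factors and nucleotide synthesis, mitosis, ATR and ATM checkpoint and homologous recombination, p53 targets, heterochromatin and Polycomb, centrosome and centriole, interferon-stimulated genes, NF-kB and inflammatory cytokines, MHC class I and antigen processing, unfolded protein and ATF4 response, glycolysis and hypoxia, cholesterol synthesis, MYC and ribosome biogenesis, WNT targets and intestinal stem cell, epithelial junction and keratin, mesenchymal transition, intestinal secretory and enterocyte, cancer-testis antigens, replication-dependent histones, and markers of fibroblasts, blood cells, hepatocyte and kidney lines, and lung and breast lines. The 20 lists with at least 5 tested genes were tested on the mean of each pair of lines with camera at a preset correlation of 0.01, adjusted over the 20 lists, and the 6 others were only described. Camera asks whether a list moves relative to the other genes. Member counts are given with the adjustment over all genes and over the list alone.

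Groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names, by size of the log2 change, the 8 highest and 8 lowest genes called in both ORC1 lines, both ORC2 lines or all 4 lines, the 6 highest and 6 lowest between ORC1 and ORC2 lines, the 3 highest and 3 lowest for each single line and for the lines of 1 mutated gene, and up to 3 called members of each list. Left out of these picks but not of the counts are symbols that begin with LOC, MIR, SNOR, SCARNA, RNU, RNY, RN7, RNA5, RPL, RPS or OR and a digit, and immunoglobulin and T cell receptor segments. Counts for the mean of the ORC1 lines and the mean of the ORC2 lines were added later.

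On data simulated from ORC1B14 and WT with 10797 genes, limma called 8%, 58%, 96% and 100% of genes planted at log2 changes of 0.5, 1, 1.5 and 2, and 8 unchanged genes. On the mean of the ORC1 lines, the 1 list shifted by 0.5 was the 1 list called. A search for runs of neighbouring genes (30 tested genes per window, changes limited to 1.5, line minus the mean of the other 4 lines, limit at the 95th percentile of the largest window in 1000 shuffled gene orders) found all 40 genes of a planted run among 10792 genes, as 1 run. This search was added after the data were seen, and was repeated on the arrays of 1 replicate number alone, taking the strongest run (genes times the size of the median). A run was kept when its median was at least 0.3 in size within both replicate numbers, a rule set after the values were seen.

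The alternatives were quantile normalization, centring each array on its median over the genes tested, no filter, a filter at the 70th percentile of mean level, the mean over a gene's probe sets, eBayes without the trend and robust, fits of only the lines compared, the replicate number as a block, each array left out in turn, line as a random block, at least 2-fold change or adjusted p under 0.01, and, for lists, camera with an estimated correlation and fry. A line left with 1 array is assumed to vary like the others. Unnamed probe sets were tested separately and their genes were not used here. No column of the value table was left out.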

Results

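Gene expression was measured in 5 lines of HCT116, an established human colorectal carcinoma line, on Affymetrix arrays that reported 53617 transcript clusters (probe sets) each. The labels name 1 wild-type line (WT), 2 lines with mutated ORC1 (ORC1B14 and ORC1BP32) and 2 with mutated ORC2 (ORC2B2 and ORC2BP8), all untreated, with 2 arrays per line and 10 arrays in total. ORC1 and ORC2 are subunits of the origin recognition complex, which binds the sites where DNA replication starts and takes part in loading the MCM helicase there. The labels do not say what kind of mutation each line carries. None of ORC1 to ORC6 (0 of 6) was named in the probe annotation used here. The mutated genes were therefore not analysed here, and the labels were not checked against them. Array medians lay between 3.87 and 3.96. Differences are given in log2 units. The log base is taken from the range of the values, since no label states it. The number of arrays limits the precision of every value.

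The first question was what the mutant lines share against WT. ADGRF1, an adhesion G protein-coupled receptor, and TRIB3, a pseudokinase induced by the stress transcription factor ATF4, fell in each of the 4 mutant lines. ADGRF1 (probe set 17019778) stood at 7.06 ± 0.42 in WT (SD, n = 2). It fell by 2.48 in ORC1B14, 2.40 in ORC1BP32, 2.70 in ORC2B2 and 2.65 in ORC2BP8 (SE 0.30, limma adjusted p = 0.0225, 0.0412, 0.00892 and 0.00516). TRIB3 (probe set 16910609) stood at 8.34 ± 0.0875 in WT and fell by 1.70, 1.99, 1.56 and 1.67 in the same order (SE 0.25, limma adjusted p = 0.0225, 0.0412, 0.0350 and 0.0128). In ORC2BP8, ADGRF1 lies in a stretch of 25 neighbouring genes on chromosome 6 with lower values in that line. The stretch had a median of -0.15 within replicate 1 and -0.83 within replicate 2, and did not meet the rule added for runs. Of 10797 genes tested, these 2 were called in 4 lines, 9 in 3 lines, 23 in 2 lines and 121 in 1 line, and no gene was called in opposite directions by 2 lines. With the replicate number as a block, which the rule set in advance did not adopt, 27 genes were called in all 4 lines. Under a stricter filter on dim probe sets ADGRF1 was not tested. The count of 2 shared genes became 0 by limma when ORC1B14 replicate 1, either ORC1BP32 array, either ORC2BP8 array or WT replicate 2 was left out, 3 others without WT replicate 1, and 0 also after quantile normalization, without the filter on dim probe sets or with a stricter one (397, 377 and 302 at an unadjusted p under 0.05). In ORC1BP32 both genes lost their calls after quantile normalization, without the filter and without any ORC1BP32, ORC2BP8 or WT array, and TRIB3 also without either ORC1B14 array (highest adjusted p 0.548 for both). In ORC1B14 both lost them without ORC1B14 replicate 1 or WT replicate 1, and TRIB3 without WT replicate 2. TRIB3 also lost its call in ORC2B2 (at -1.96 to -1.16) without either WT array, either ORC1BP32 array or ORC2B2 replicate 1, and in ORC2BP8 without either WT array or ORC2BP8 replicate 2, while ADGRF1 kept its call there and in ORC2B2 without each of the 10 arrays. At an unadjusted p under 0.05, 359 genes differed the same way in all 4 lines, where simulated unchanged lines set against the same WT arrays gave a mean of 23.4 and at most 38. Between 189 and 382 did so without the arrays that gave 0. The simulation was read at this p only after the data were seen, and it does not cover a WT line that itself differs. It drew each gene on its own, so it also does not cover shifts that many genes share on an array. Its highest count may therefore be too low.

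**Figure D1:**
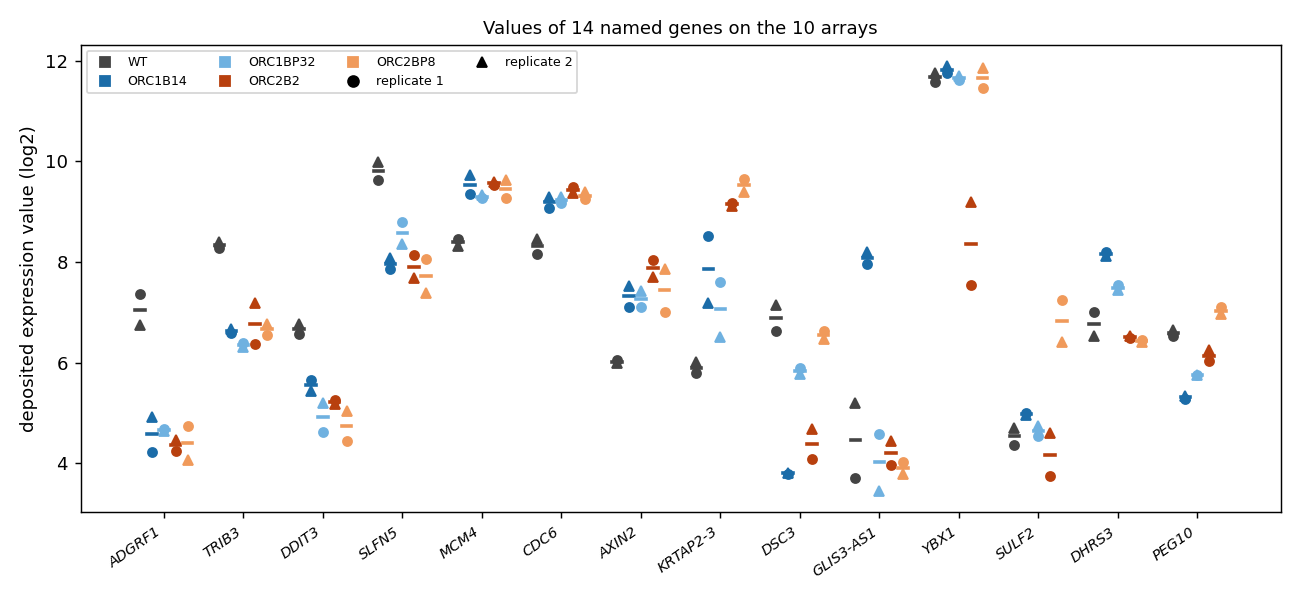
Deposited log2 value (vertical axis) of 14 genes named in the text on each of the 10 arrays, with circles for replicate 1, triangles for replicate 2 and a bar for the mean of each line. ADGRF1 averaged 7.06 in WT and between 4.36 and 4.66 in the mutant lines, and YBX1 averaged 8.37 in ORC2B2 and between 11.65 and 11.83 in the other lines.

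Pairs of lines shared more calls than independent lists would, though independent lists do not allow for the WT arrays that the comparisons share. The ORC2 lines ORC2B2 and ORC2BP8 shared 7 higher and 12 lower genes, where independent lists would share 0.0325 and 0.158. Simulated unchanged lines set against the same WT arrays shared 0.01. Lines without changes have almost no calls at this threshold, so that value cannot tell how many calls changed lines share through the WT arrays. ORC1B14 shared 5 higher and 16 lower genes with ORC2BP8, and 4 higher and 12 lower with ORC2B2, against 0.05, 0.295, 0.0241 and 0.0916 for independent lists. The ORC1 lines ORC1B14 and ORC1BP32 shared 0 higher and 2 lower genes by limma, where independent lists would share 0 and 0.00797. At an unadjusted p under 0.05 they shared 684 genes of the same direction, against a mean of 116 and at most 155 for simulated unchanged lines with the same WT arrays. The ORC2 lines shared 728. With ORC2B2 and ORC2BP8, ORC1B14 shared 744 and 830 and ORC1BP32 549 and 597, so lines of 1 mutated gene did not stand apart. These simulations do not cover shifts that many genes share on an array, so such limits may be too low. Across genes, which are not independent replicates, the log2 changes of the ORC1 lines correlated at 0.736 against 0.5 for simulated unchanged lines, with a covariance of 0.105 against 0.0308. For the ORC2 lines the correlation was 0.709 against 0.499, and the covariance 0.105 against 0.0308, a difference of 0.0742. With ORC2B2 and ORC2BP8, ORC1B14 correlated at 0.717 and 0.689, with covariances of 0.112 and 0.116. ORC1BP32 correlated with them at 0.685 and 0.673, with covariances of 0.086 and 0.0908. The 2 lines of a pair were then taken on different replicate numbers, each minus the WT array of its own number. No WT array was shared in this way, though the WT line was. The covariance was 0.0580 and 0.0883 for the ORC1 lines and 0.0872 and 0.0773 for the ORC2 lines, and between 0.0429 and 0.128 for the other pairs. This check was chosen after the data were seen.

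Each ORC1 line was then compared with WT. In ORC1B14, GLIS3-AS1 rose by 3.62 (SE 0.45, limma adjusted p = 0.0225). Its WT values were 3.72 and 5.20, the first below the median of that array, so the size of this change is uncertain. GLIS3, the zinc-finger transcription factor gene that GLIS3-AS1 runs antisense to, rose by 2.56. THBS1, the secreted glycoprotein thrombospondin 1, rose by 2.63. DSC3, a desmosomal cadherin, fell by 3.09 (SE 0.24, adjusted p = 0.000830), from 6.89 ± 0.35 to 3.80 ± 0.00676 (SD, n = 2). The last level lies below the medians of those arrays, so the size of this change is uncertain. NETO2 fell by 2.65, and the growth factor gene FGF9 fell by 2.59. In ORC1BP32, ORC2B2 and ORC2BP8, FGF9 stood at -2.11, -1.64 and -2.22 against WT, and THBS1 at 1.10, 1.97 and 1.165. GLIS3-AS1 (-0.44, -0.25 and -0.55) and NETO2 (0.04, -0.41 and 0.60) did not follow ORC1B14 in this way. In all, 20 genes rose and 43 fell in ORC1B14, 57 of these 63 by at least 2-fold. Of the 43 that fell, 6 belong to a run of 45 neighbouring genes on chromosome 5 with lower values in that line (GPBP1, ELOVL7, ERBIN, KGD4, CDK7 and RAD17, named here after their values were seen). In ORC1BP32 the called genes were ADGRF1 and TRIB3, so 0 genes rose and 2 fell by limma. There 1090 genes reached an unadjusted p under 0.05 (570 higher, 520 lower), and 1831 did in ORC1B14 (880 higher, 951 lower). With the replicate number as a block 57 genes were called in ORC1BP32 and 496 in ORC1B14. The count in ORC1B14 was 1 without its own replicate 1, 9 without WT replicate 1, 4 without WT replicate 2, 22 without either ORC1BP32 array and 36 without either ORC2B2 array. DSC3 kept its call without each of the 10 arrays, and the other 5 genes lost theirs without ORC1B14 replicate 1 (highest adjusted p 0.163 for GLIS3-AS1, 0.213 for GLIS3, 0.190 for THBS1, 0.170 for NETO2 and 0.178 for FGF9). All but GLIS3-AS1 also lost it without either WT array, GLIS3 and NETO2 without either ORC1BP32 array and GLIS3 without ORC1B14 replicate 2. As the mean over its probe sets GLIS3 stood at 1.39 without a call (adjusted p = 0.0853). The count in ORC1BP32 was 0 without either of its own arrays, either ORC2BP8 array or WT replicate 2, and 5 without either ORC2B2 array.

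In the mean of both ORC1 lines 10 genes rose and 19 fell, a count added after the data were seen. The directions were nearer to even after quantile normalization (26 and 29), after centring (21 and 31) and at an unadjusted p under 0.05 (883 and 878). ADGRF1 fell by 2.44, DSC3 by 2.07 and TRIB3 by 1.85 (SE 0.26, 0.21 and 0.22, limma adjusted p = 0.00878, 0.00878 and 0.0124). Chosen after their values were seen, FGF9 fell by 2.35, PCDH7, a protocadherin, fell by 2.04, and the keratin gene KRT80 rose by 1.91 (adjusted p = 0.0263, 0.0124 and 0.0387). PCDH7 stood at 3.68 in ORC1B14 and 3.76 in ORC1BP32, below the array medians, so the size of its change is uncertain, as is that of DSC3 in ORC1B14. This count was 2 without ORC1B14 replicate 1, 2 and 12 without ORC1BP32 replicates 1 and 2, 18 without either ORC2B2 array, 9 without WT replicate 1 and 0 without WT replicate 2, where 1198 genes had an unadjusted limma p under 0.05. Without WT replicate 2 each of these 6 genes lost its call, ADGRF1, TRIB3, FGF9 and KRT80 also without WT replicate 1, and TRIB3, FGF9, PCDH7 and KRT80 without replicate 1 of either ORC1 line. FGF9 also lost it without ORC1BP32 replicate 2, and KRT80 without either ORC2BP8 array.

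Each ORC2 line was compared with WT in the same way, and 19 genes were called in both ORC2 lines. KRTAP2-3, a keratin-associated protein gene (probe set 16844585), rose by 3.24 in ORC2B2 and 3.63 in ORC2BP8 (SE 0.41, limma adjusted p = 0.0145 and 0.00516), from 5.90 ± 0.15 in WT to 9.15 ± 0.0437 and 9.53 ± 0.19 (SD, n = 2). Averaged over both lines, the other 6 shared higher genes were PLK2, a polo-like kinase (1.94), AXIN2, a WNT-induced scaffold of the beta-catenin destruction complex (1.64), SDF2L1, part of a chaperone complex of the endoplasmic reticulum (1.30), the MCM helicase subunit gene MCM4 (1.11), CDC6, which loads the MCM helicase (1.06), and MEA1 (0.94). The lower genes, ordered by size, were led by ADGRF1 (-2.67), the Schlafen gene SLFN5 (-2.0), the transcription factor gene KLF7 (-1.81), ANTXR2, an anthrax toxin receptor (-1.73), ANKRD22 (-1.70), DDIT3, the stress transcription factor CHOP (-1.68), TCP11L2 (-1.63) and TRIB3 (-1.62). For these 15 mean changes SE lay between 0.15 and 0.36. These 15 genes also stood in the same direction in both ORC1 lines, and none of them was called between ORC1 and ORC2 lines. In ORC1B14 and ORC1BP32, KRTAP2-3 stood at 1.96 and 1.16, AXIN2 at 1.30 and 1.24, and SLFN5 at -1.85 and -1.24. ANTXR2 stood there at -1.61 and -0.67. The 19 shared genes, 17 of them changed at least 2-fold in both lines, became 4 without either ORC1BP32 array, 8 and 4 without ORC2B2 replicates 1 and 2, 7 without ORC2BP8 replicate 2, 7 without WT replicate 1 and 2 without WT replicate 2. As changes of the mean of both ORC2 lines, those of KRTAP2-3 and ADGRF1 kept their calls without each of the 10 arrays, while the other 13 lost theirs without WT replicate 1 (ANTXR2), WT replicate 2 (SLFN5 and ANKRD22) or either WT array, and MEA1 also without ORC2BP8 replicate 2 (highest adjusted p 0.163, for MCM4 and MEA1). In ORC2B2 alone KRTAP2-3 lost its call without either WT or either ORC2B2 array (highest adjusted p 0.0739). ANKRD22 stood between 2.80 and 3.10 in the mutant lines, below the array medians, so the size of its change is uncertain. PLK2 also rose in ORC1B14, by 1.79, inside the chromosome 5 run of lower genes. KRTAP2-3 lies among 22 neighbouring keratin and other genes on chromosome 17, whose median difference from WT was 0.47 in both ORC2B2 and ORC2BP8.

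Other changes were called in a single ORC2 line, although some of these genes moved the same way in other lines. In ORC2B2, YBX1, a nucleic-acid-binding Y-box protein gene, fell by 3.30 (SE 0.39, limma adjusted p = 0.0116), from 11.67 ± 0.13 in WT to 8.37 ± 1.18 (SD, n = 2). DSC3 fell by 2.50, the keratin gene KRT23, in the chromosome 17 stretch of KRTAP2-3, rose by 3.22 and SYTL2, a vesicle traffic gene, rose by 2.51 (adjusted p = 0.00472, 0.0323 and 0.0449). DSC3 lies there in a run of 26 neighbouring genes on chromosome 18 with lower values in ORC2B2. In ORC2BP8, SMAD7, an inhibitor of TGF-beta signalling, rose by 2.40 and KRT80 by 2.31, while the synaptotagmin gene SYT1 fell by 2.91 and LURAP1L by 2.65 (adjusted p = 0.00539, 0.0144, 0.00516 and 0.00794). In ORC1B14, ORC1BP32 and ORC2B2, SYT1 stood at -1.57, -2.10 and -1.48 against WT, and LURAP1L at -1.77, -1.10 and -1.68. There KRT80 stood at 2.06, 1.75 and 0.84, and SMAD7 at 0.58, 0.74 and 0.76. YBX1 lay between -0.02 and 0.16 in the lines other than ORC2B2. In all, 13 genes rose and 23 fell in ORC2B2 (35 of 36 by at least 2-fold), and 27 rose and 74 fell in ORC2BP8 (86 of 101). At an unadjusted p under 0.05 the directions were near even, with 628 higher and 634 lower of 1262 in ORC2B2, and 800 higher and 772 lower of 1572 in ORC2BP8. With the replicate number as a block 251 genes were called in ORC2B2 and 402 in ORC2BP8. Of the 74 that fell in ORC2BP8, 15 belong to a run of 222 neighbouring genes on chromosome 16 with lower values in that line. The count in ORC2B2 was 8 without either ORC1BP32 array, 17 and 11 without its own replicates 1 and 2, and 10 and 7 without WT replicates 1 and 2. The count in ORC2BP8 was 57 and 55 without ORC1BP32 replicates 1 and 2, 156 and 19 without its own replicates 1 and 2, and 37 and 14 without WT replicates 1 and 2. In ORC2B2, DSC3 kept its call without each of the 10 arrays and YBX1 lost it without WT replicate 2 (highest adjusted p 0.0716). KRT23, at 2.33 to 4.11, lost it without either ORC1BP32 array, ORC2B2 replicate 2 or either WT array (highest adjusted p 0.138), and SYTL2 without any ORC1 or ORC2B2 array or WT replicate 1 (0.189). In ORC2BP8, SYT1 kept its call without each array, while SMAD7 lost it without WT replicate 2 (0.0540), LURAP1L without ORC2BP8 replicate 2 (0.0649) and KRT80 without either ORC2BP8 or either WT array (0.0941). In the mean of both ORC2 lines, a count added after the data were seen, 32 genes rose and 83 fell, against 72 and 102 after quantile normalization, 74 and 123 after centring, and 826 and 812 at an unadjusted p under 0.05. The count was 64 without either ORC1BP32 array, 74 and 56 without ORC2B2 replicates 1 and 2, 267 and 35 without ORC2BP8 replicates 1 and 2, and 25 and 5 without WT replicates 1 and 2.

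Gene lists fixed in advance showed the replication and cell-cycle genes together. In the mean of both ORC1 lines against WT, the list of origin licensing and MCM helicase genes rose by a median of 0.73, with 11 of 13 members above 0 (camera adjusted p = 1.57e-06, and adjusted p = 0.447 with an estimated correlation). MCM4 rose by 1.02 and CDC6 by 0.90 (SE 0.16 and 0.15, limma adjusted p = 0.0373 and 0.0449), so 2 members were called over all genes and 8 were higher when adjusted over the list alone. CDC6 lost its call without each of the 10 arrays (adjusted p between 0.0504 and 0.282), and MCM4 without ORC1B14 replicate 1 or any ORC1BP32, ORC2B2 or WT array (highest 0.231). The list of replication initiation and fork genes rose by a median of 0.52 with 18 of 18 above 0 (camera adjusted p = 1.1e-06, and adjusted p = 0.488 with an estimated correlation). In it 0 members were called by limma over all genes and 7 higher when adjusted over the list alone. PCNA, the sliding clamp of the replication fork, differed by 0.72 (limma adjusted p = 0.108). The G1/S list of cyclins, E2F factors and nucleotide synthesis rose by 0.44 with 20 of 25 above 0 (adjusted p = 7.08e-06, and adjusted p = 0.447 with an estimated correlation; 0 called over all genes, 11 higher and 1 lower adjusted over the list alone). The mitosis list rose by 0.35 with 31 of 32 above 0 (adjusted p = 5.28e-09, and adjusted p = 0.344 with an estimated correlation; 0 members called by limma over all genes, 10 higher adjusted over the list alone).

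Stress, sterol and interferon lists were also called in the ORC1 lines. The unfolded protein and ATF4 list fell, with a median of -0.61 and 11 of 13 members below 0 (camera adjusted p = 5.53e-05, and adjusted p = 0.447 with an estimated correlation). In it TRIB3, DDIT3 (-1.43) and ASNS, the asparagine synthetase gene (-1.39), fell, SDF2L1 rose by 1.03 (limma adjusted p = 0.0357, 0.0449 and 0.0385 for the last 3), and 1 member was higher and 7 lower when adjusted over the list alone. TRIB3, DDIT3, ASNS and SDF2L1 kept their calls without 6, 3, 3 and 2 of the 10 arrays, each losing it without either WT array and replicate 1 of either ORC1 line. The cholesterol synthesis list rose by a median of 0.47 with 12 of 16 above 0 (camera adjusted p = 9.5e-05, and adjusted p = 0.344 with an estimated correlation). In it 0 members were called by limma over all genes and 9 higher when adjusted over the list alone, among them DHCR7, a reductase of the last steps (0.79, limma adjusted p = 0.0658). The interferon-stimulated list rose by a median of 0.45 with 19 of 21 above 0 (camera adjusted p = 0.00051, and adjusted p = 0.771 with an estimated correlation; 0 members called by either adjustment, with IFIT1 at 1.49 and limma adjusted p = 0.206). Most of this rise lay in ORC1BP32: the median against WT was 0.72 there and 0.09 in ORC1B14, with 1.28 on ORC1BP32 replicate 1 and 0.28 on its replicate 2. Its median was 1.03 between arrays of replicate 1 and 0.00555 between those of replicate 2, and 0.2415 without WT replicate 1, where the camera adjusted p was 0.0574.

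The same lists were tested in the mean of both ORC2 lines. Origin licensing rose by a median of 0.73 with 12 of 13 members above 0, replication initiation and fork by 0.70 with 18 of 18, G1/S by 0.45 with 23 of 25, and mitosis by 0.49 with 31 of 32 (camera adjusted p = 1.28e-07, 5.67e-11, 1.19e-07 and 1.67e-12; adjusted p = 0.30 with an estimated correlation for each of these 4). Over all genes 2, 0, 2 and 1 members were called higher by limma, against 6, 11, 12 and 16 when adjusted over the list alone. These included TYMS, thymidylate synthase (0.94), UHRF1, which maintains DNA methylation at replication (0.79), and FOXM1, a transcription factor of mitotic genes (0.78), with limma adjusted p = 0.0441, 0.0441 and 0.0423. RBL2, a pocket protein that represses E2F targets, fell by 0.95 within the G1/S list (adjusted p = 0.0361). It lies in the chromosome 16 run and stood at -1.49 in ORC2BP8. TYMS, UHRF1, FOXM1 and RBL2 each lost the call without any ORC1BP32, ORC2B2 or WT array or ORC2BP8 replicate 2 (highest adjusted p 0.337, 0.263, 0.313 and 0.220), and the first 3 also without the filter and without the trend. The ATF4 list fell by a median of -0.65 with 11 of 13 below 0 (camera adjusted p = 1.29e-06, and adjusted p = 0.30 with an estimated correlation). Of its members DDIT3 fell by 1.68, TRIB3 by 1.62 and DDIT4, a stress-induced inhibitor of mTORC1, by 1.54 (SE 0.22, 0.22 and 0.24). SDF2L1 rose, and 1 member was higher and 5 lower over all genes, 1 and 7 over the list alone.

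The cholesterol list rose by a median of 0.38 in the ORC2 lines with 12 of 16 above 0 (camera adjusted p = 0.00987, and adjusted p = 0.30 with an estimated correlation; 0 members by limma over all genes, 5 higher and 1 lower adjusted over the list alone). The camera adjusted p was 0.0594 without ORC2B2 replicate 1, 0.0760 without ORC2BP8 replicate 1 and 0.182 without WT replicate 2. The ATR and ATM checkpoint and homologous recombination list rose by a median of 0.19 with 16 of 26 above 0 (camera adjusted p = 0.0233, and adjusted p = 0.617 with an estimated correlation; 0 members by limma over all genes, 2 higher adjusted over the list alone). Its adjusted p was 0.175 without WT replicate 1, 0.0934 without ORC2B2 replicate 1 and 0.0646 without ORC2BP8 replicate 2. With camera and an estimated correlation 0 of 20 lists were called in either comparison, and the lowest adjusted p was 0.344 for the ORC1 and 0.30 for the ORC2 lines. By fry, which asks whether a list's genes move 1 way on balance, mitosis (adjusted p = 0.0451) and cholesterol synthesis (0.0451) were called in the ORC1 lines and mitosis (0.0334) in the ORC2 lines. Measured per array, the medians of the licensing, replication, G1/S, mitosis and cholesterol lists lay above both WT arrays in 8 of 8 mutant arrays, and that of the ATF4 list below both WT arrays in 8 of 8.

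**Figure D2:**
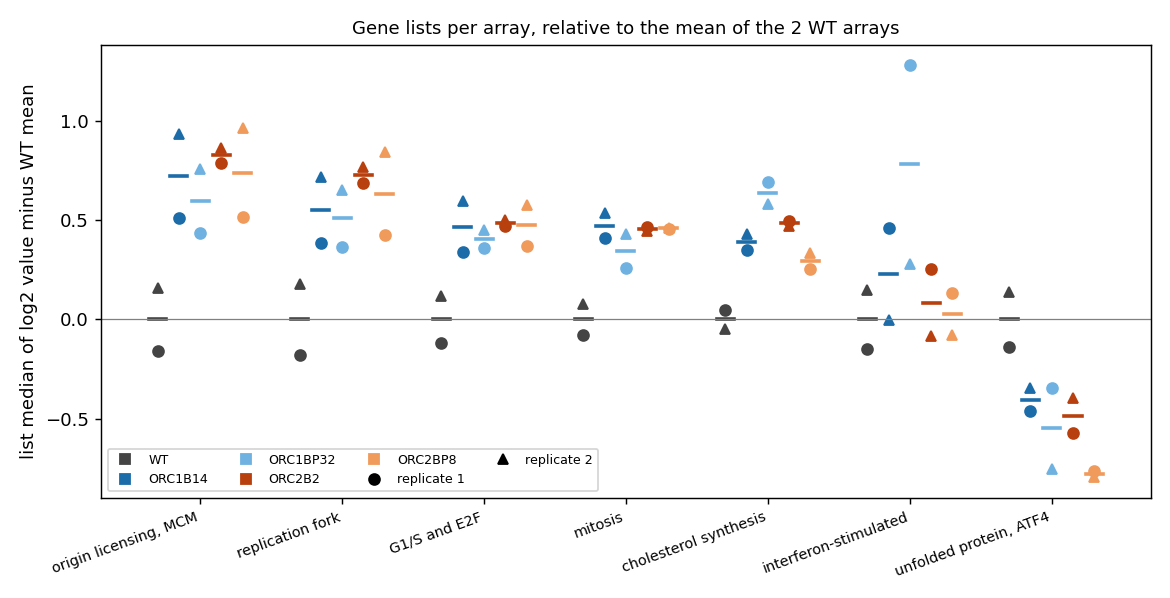
Median of log2 value minus the WT mean over the members of 7 gene lists (vertical axis, log2 units) on each of the 10 arrays, with circles for replicate 1, triangles for replicate 2 and a bar for the mean of each line. For the licensing list the mutant arrays lie between 0.44 and 0.97 and the WT arrays at -0.16 and 0.16, and for the ATF4 list the mutant arrays lie between -0.79 and -0.35.

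The ORC1 lines were set against the ORC2 lines, a comparison that does not use WT levels. DHRS3, a retinal reductase, was higher in the ORC1 lines by 1.36, the adhesion molecule gene CNTN1 by 1.07 and STK39, a kinase that regulates ion cotransporters, by 0.79 (SE 0.14, 0.14 and 0.10, limma adjusted p = 0.0112, 0.0267 and 0.0252). PEG10, an imprinted gene derived from a retrotransposon, was lower in the ORC1 lines (-1.06, SE 0.13, adjusted p = 0.0211). The fifth gene called was MIR4527, also lower (adjusted p = 0.0112), which lies outside the naming rule and was chosen after its values were seen. Mean levels of DHRS3 were 8.17 ± 0.0605 and 7.50 ± 0.0829 in ORC1B14 and ORC1BP32, against 6.51 ± 0.0172, 6.44 ± 0.0272 and 6.77 ± 0.34 in ORC2B2, ORC2BP8 and WT (SD, n = 2). CNTN1 stood at 3.88 in ORC2BP8, near the array medians, and between 5.18 and 5.90 in the other lines, and MIR4527 at 5.40 in ORC2BP8 and between 2.24 and 2.48 in the other lines, below the array medians, so the size of its difference is not given. The 5 calls became 1 without ORC1B14 replicate 1, 0 by limma without either ORC1BP32 array (488 and 808 genes at an unadjusted p under 0.05), 10 without ORC2B2 replicate 1, and 3 and 1 without ORC2BP8 replicates 1 and 2. DHRS3 kept its call without 6 of the 10 arrays, PEG10 without 3, CNTN1 without 2 and STK39 without 1. With line as a random term all 4 lost their calls (adjusted p = 0.0600, 0.453 and 0.0600 for DHRS3, CNTN1 and STK39, 0.254 for PEG10).

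Of the 20 lists 7 differed between ORC1 and ORC2 lines by camera. The interferon-stimulated list was higher in the ORC1 lines by a median of 0.52 with 20 of 21 members above 0 (camera adjusted p = 3.22e-07, and adjusted p = 0.604 with an estimated correlation; 0 members by limma over all genes and 5 adjusted over the list alone). Against the mean of the ORC2 lines its median was 0.61 in ORC1BP32 and 0.19 in ORC1B14. The NF-kB and cytokine list was higher by 0.19 with 9 of 10 above 0, glycolysis and hypoxia by 0.16 with 13 of 15, p53 targets by 0.15 with 10 of 13 and cholesterol synthesis by 0.11 with 12 of 16 (camera adjusted p = 0.00717, 0.00717, 0.0244 and 0.0466; adjusted p = 0.415, 0.308, 0.347 and 0.604 with an estimated correlation). Replication initiation and fork was lower with a median of -0.18 and 14 of 18 below 0, and the ATR and ATM list with -0.10 and 18 of 26 (camera adjusted p = 0.0244 for both, and adjusted p = 0.751 with an estimated correlation for both). In these 6 lists 0 members were called by limma over all genes, and 1 NF-kB and 1 cholesterol member when adjusted over the list alone. Fry called p53 targets (adjusted p = 0.0133) and glycolysis (0.0335). Over all genes 446 higher and 306 lower had an unadjusted p under 0.05.

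Leaving out single arrays ended most of these list differences. Replication was lost without ORC1B14 replicate 1, ORC1BP32 replicate 1 or ORC2BP8 replicate 2 (camera adjusted p = 0.349, 0.247 and 0.550). The ATR and ATM median was 0.0006562 without ORC1B14 replicate 1 (adjusted p = 0.526), and its call was lost without ORC1BP32 replicate 1, ORC2B2 replicate 1 or ORC2BP8 replicate 2 (0.365, 0.174 and 0.158). NF-kB was lost without ORC1B14 replicate 1 or ORC1BP32 replicate 1 (0.193 and 0.0634), p53 targets without ORC1BP32 replicate 2 or ORC2BP8 replicate 2 (0.0513 and 0.0674), and cholesterol synthesis without either WT array, ORC1BP32 replicate 1, ORC1B14 replicate 2, ORC2B2 replicate 2 or ORC2BP8 replicate 2 (between 0.0857 and 0.208). The interferon and glycolysis lists kept their calls without each of the 10 arrays, but the interferon median was 0.20 without ORC1BP32 replicate 1 (adjusted p = 0.0109) and 0.71 without its replicate 2.

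The lines with the same mutated gene were compared with each other as a yardstick. Between the ORC1 lines, GLIS3-AS1 was higher in ORC1B14 by 4.05 (SE 0.45) and DSC3 was lower there (-2.03, SE 0.24, limma adjusted p = 0.0254 for both), at a level below the array medians, and these were the 2 genes called, with 574 at an unadjusted p under 0.05. GLIS3-AS1 stood at 4.59 and 3.46 in ORC1BP32, the second below the median of that array, so the size of its difference is uncertain. Between the ORC2 lines 24 genes were called, 15 higher and 9 lower in ORC2B2, with 589 at an unadjusted p under 0.05. The non-coding RNA CRNDE was higher in ORC2B2 by 2.28, the necroptosis gene MLKL by 2.25 and the metallothionein gene MT1F by 1.82 (SE 0.33, 0.26 and 0.24, adjusted p = 0.0243, 0.00777 and 0.0176); all 3 lie in the chromosome 16 run that is lower in ORC2BP8. CRNDE stood at 3.80 there, below the array medians, so the size of its difference is uncertain. Lower in ORC2B2 were YBX1 (-3.28), SULF2, an extracellular sulfatase gene (-2.66), and GRHL2, an epithelial transcription factor gene (-2.20). Their SE were 0.39, 0.31 and 0.25, with limma adjusted p = 0.00817, 0.00817 and 0.00777. SULF2 lay between -3.08 and -1.19 over all alternatives, and between -3.08 and -2.235 with 1 array left out, so its size depends on the processing. The 2 calls between the ORC1 lines became 0 without ORC1B14 replicate 1, ORC1BP32 replicate 2 or either ORC2BP8 array (between 363 and 608 at an unadjusted p under 0.05), 1 without ORC1BP32 replicate 1, 4 without ORC1B14 replicate 2 and 5 without either ORC2B2 array. The 24 became 11 and 8 without ORC2B2 replicates 1 and 2, and 2 and 4 without ORC2BP8 replicates 1 and 2.

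**Figure D3:**
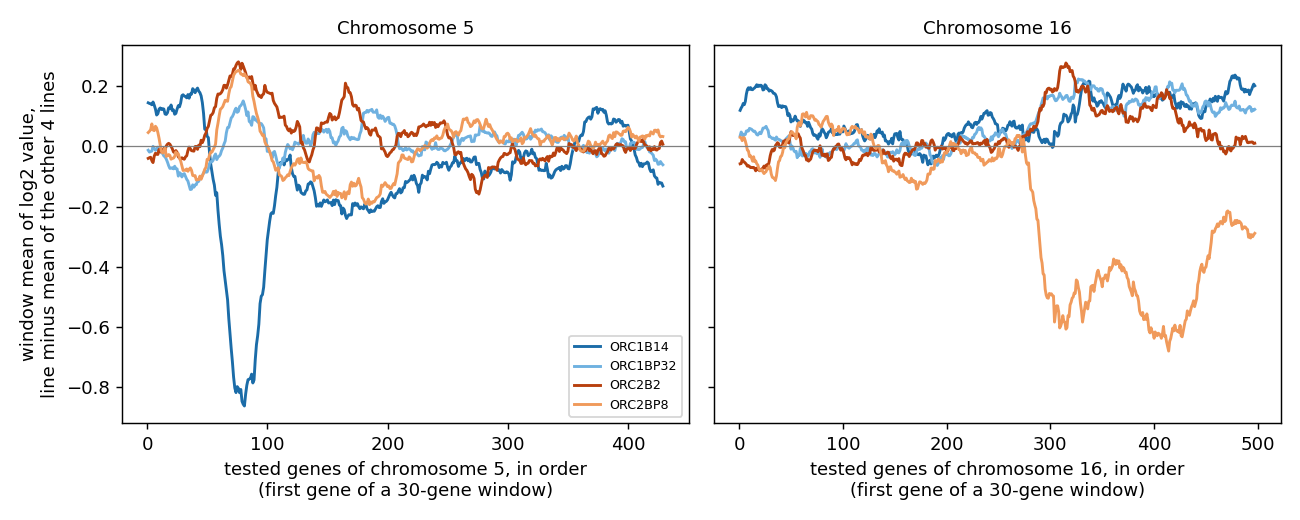
Mean over 30 neighbouring tested genes of the log2 difference between a line and the mean of the other 4 lines (vertical axis), along the gene order of chromosomes 5 and 16 (horizontal axis), with 1 curve per line. ORC1B14 dips on chromosome 5 over a run of 45 genes with a median of -0.74, and ORC2BP8 on chromosome 16 over 222 genes with a median of -0.38.

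The remaining lists were not called against WT. ATR and ATM checkpoint genes had a median of 0.13 in the ORC1 lines, and interferon-stimulated genes 0.04 in the ORC2 lines. In the ORC1 and the ORC2 lines respectively, medians were 0.10 and -0.07 for p53 targets, 0.07 and 0.19 for heterochromatin and Polycomb genes, -0.06 and 0.13 for centrosome genes, 0.10 and -0.12 for NF-kB and cytokine genes, 0.12 and -0.02 for glycolysis and hypoxia, and 0.01 and 0.10 for MYC and ribosome biogenesis. They were -0.03 and -0.08 for WNT targets and intestinal stem cell genes, -0.13 and -0.17 for epithelial junction and keratin genes, 0.15 and 0.19 for mesenchymal transition genes, and 0.07 and 0.05 for intestinal secretory and enterocyte genes. Camera adjusted p lay between 0.393 and 0.998 in the ORC1 lines and between 0.109 and 0.999 in the ORC2 lines. Single members of uncalled lists changed in the ORC2 lines. AXIN2, a WNT target, rose. In the epithelial list the keratin gene KRT20, in the chromosome 17 stretch of KRTAP2-3, rose by 1.31, while GRHL2 and ESRP1, an epithelial splicing regulator, fell by 1.38 and 0.97. For GRHL2 and KRT20 this lay mostly in ORC2B2 (-2.48 and 1.99, against -0.28 and 0.63 in ORC2BP8). Among p53 targets SESN2, which the ATF4 list also holds, fell by 1.18 (limma adjusted p = 0.0441, 0.0179, 0.0396 and 0.0395 for the last 4). With 1 array left out, KRT20, GRHL2, ESRP1 and SESN2 kept their calls in 2, 7, 4 and 5 of 10 fits, each losing it without either WT array or ORC2BP8 replicate 2. Adjusted over the list alone, 1 WNT member, 1 epithelial member and 1 p53 target were higher and 0, 2 and 2 were lower. Median, mean and test differed in sign in the ORC1 lines for the centrosome list (mean 0.02, test up) and the WNT list (mean 0.08, test up), and in the ORC2 lines for interferon (test down), WNT (mean 0.16, test up) and intestinal secretory genes (mean -0.00880, test down). Between ORC1 and ORC2 lines 13 lists were not called, with camera adjusted p between 0.0612 and 0.839, and the ATF4 list had a median of -0.01 with a mean of 0.11 and a test up.

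Markers of other cell types were not called. Hepatocyte and kidney line markers had medians of 0.05 and 0.02 in the ORC1 and ORC2 lines over 7 genes tested (means -0.06 and -0.12, tests up and down, camera adjusted p = 0.998 and 0.773). Lung and breast line markers had medians of 0.07 and -0.10 over 6 genes (means -0.02 and -0.01, both tests down, camera adjusted p = 0.998 and 0.773). GATA3 is in both lists. Between ORC1 and ORC2 lines their medians were -0.00344 and 0.03, with means of 0.07 and -0.00154 and both tests up. Lists with fewer than 5 tested genes were not tested, and their levels over all named probe sets follow. The median WT and mutant levels were 3.73 and 3.75 for 6 blood cell markers (highest CD68, 8.47), 3.11 and 3.10 for 4 fibroblast markers (highest THY1, 4.46), 2.97 and 3.18 for 7 cancer-testis antigens, and 8.42 and 8.33 for 4 MHC class I and antigen processing genes. LRWD1, the 1 named member of the origin recognition complex list, stood at 6.94 in WT and 7.37 in the mutant lines. Replication-dependent histone genes had 0 named members.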

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

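The tests on the interferon list, the count of divisions at an unadjusted p and the tests of divisions with the replicate number as a term were chosen only after the results were seen. The other divisions of the mutant arrays and of the lines were planned.

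Genes stood out where the difference between groups of mutant lines itself passed its test. Between the ORC1 and the ORC2 lines these were DHRS3 (1.36), CNTN1 (1.07), STK39 (0.79) and PEG10 (-1.06). DHRS3 lost its call without ORC1B14 replicate 1, either ORC1BP32 array or ORC2BP8 replicate 2 (highest adjusted p over left-out arrays 0.0780). CNTN1, STK39 and PEG10 lost theirs without 8, 9 and 7 of the 10 arrays (highest 0.144, 0.144 and 0.129). With line as a random term all 4 lost their calls (adjusted p = 0.0600, 0.453, 0.0600 and 0.254). Between ORC1B14 and ORC1BP32 they were GLIS3-AS1 (4.05) and DSC3 (-2.03). Both calls were lost without either ORC1B14 array, ORC1BP32 replicate 2 or either ORC2BP8 array, and that of DSC3 also without ORC1BP32 replicate 1 (highest adjusted p 0.302 and 0.326).

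Between ORC2B2 and ORC2BP8 the genes were CRNDE (2.28), MLKL (2.25), MT1F (1.82), YBX1 (-3.28), SULF2 (-2.66) and GRHL2 (-2.20). CRNDE lost its call without any array of these lines (highest adjusted p 0.151) and SULF2 without ORC2BP8 replicate 1 (0.0600). MLKL lost it without ORC2B2 replicate 2 or ORC2BP8 replicate 1 (0.0600), and GRHL2 without replicate 1 of either line (0.0600). MT1F lost it without either ORC2B2 array or ORC2BP8 replicate 2 (0.135), and YBX1 without either ORC2BP8 array (0.114). The arrays of ORC2B2 had an SD of 1.18 for YBX1 (n = 2), so the size of that change is poorly fixed. SULF2 lay between -3.08 and -1.19 over all alternatives, so the size of its difference is uncertain. CRNDE in ORC2BP8, DSC3 in ORC1B14 and GLIS3-AS1 on ORC1BP32 replicate 2 lie below the array medians, so the sizes of their differences are uncertain too.

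Gene lists stood out in the same way between the ORC1 and the ORC2 lines. Their medians were 0.52 for interferon-stimulated genes, 0.19 for NF-kB and cytokines, 0.16 for glycolysis and hypoxia, 0.15 for p53 targets, 0.11 for cholesterol synthesis, -0.18 for replication initiation and fork, and -0.10 for the ATR and ATM list. With an estimated correlation camera called 0 of these 7.

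Probe sets that carry no gene name here were outside the comparisons of genes. Of 17829 tested, limma called 2 in ORC1B14 (0 higher), 3 in ORC1BP32 (2 higher, the largest by 4.55), 1 in ORC2B2 (0 higher) and 8 in ORC2BP8 (1 higher). What they measure was not analysed here.

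The interferon list was higher in the ORC1 lines than in the ORC2 lines by a median of 0.52, which was 0.20 without ORC1BP32 replicate 1. Within replicate 1 the median was 0.55 and within replicate 2 it was 0.30, which argues against arrays of 1 replicate number as the whole cause. Against the mean of the ORC2 lines the median was 0.61 in ORC1BP32 but 0.19 in ORC1B14, so the difference may belong to ORC1BP32 more than to mutated ORC1. An effect of the mutated gene stays open, since each gene is represented by 2 lines that may also differ in other ways.

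The 8 mutant arrays were also divided in all 35 ways into groups of 4, in a fit of 2 groups. The true division into ORC1 and ORC2 lines gave 0 genes by limma (632 at an unadjusted p under 0.05), and the highest of the others gave 8. A count of 0 is reached by 35 of 35 divisions whatever the data, so for called genes this test decides nothing. By genes at an unadjusted p under 0.05, 12 of 35 divisions gave as many as the true one, and for lists the true division gave 6, reached by 8 of 35, with 12 as the highest of the others, so chance cannot be excluded for these counts. The division with 8 genes follows the replicate number (1863 at an unadjusted p under 0.05), which points to a structure of the samples by number that this fit ignores. With the number as a term, 18 divisions hold 2 arrays of each number in both groups, too few for a share under 0.05. Of these the true one gave 0 genes by limma (867 at an unadjusted p under 0.05) and 6 lists, and the highest of the others 2 genes and 10 lists. With the 5 line means, the 3 ways to pair the lines gave 5 genes for the true pairs, 4 for ORC1B14 with ORC2B2 and 1 for ORC1B14 with ORC2BP8, and 7, 1 and 2 lists.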

How the results depend on the processing

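Counts for the mean of the ORC1 lines and the mean of the ORC2 lines were added after the data were seen, so their tests under each alternative were chosen afterwards. The cause was not tested for the changes given here, unless stated.

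Of 91 calls of named genes, 89 held after quantile normalization, 91 after centring, 90 with the mean over probe sets, 90 with robust eBayes, 78 without the trend, 73 without the filter, 63 of 64 with the stricter filter and 19 of 24 with only the lines compared. Without WT replicate 1 32 held, and without WT replicate 2 24. Calls that held in every setting that tested them were 8: KRTAP2-3 and ADGRF1 in the mean of the ORC2 lines, ADGRF1 in ORC2B2 and ORC2BP8, DSC3 in ORC1B14 and ORC2B2, and KRTAP2-3 and SYT1 in ORC2BP8. ADGRF1 did not pass the stricter filter, so its calls were not tested there. Of 21 calls of lists, 21 held under both scalings and both filters and 20 with the mean over probe sets, while 5 held with fry and 0 with an estimated correlation. Robust eBayes does not enter the list test and says nothing about it.

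Quantile normalization gave 0 genes in ORC1BP32, in both ORC1 lines and in all 4 lines (limma; 1197, 767 and 397 at an unadjusted p under 0.05). It gave 55 in the mean of the ORC1 lines (26 higher, 29 lower) and 174 in that of the ORC2 lines (72 higher, 102 lower). Centring gave 7 in ORC1BP32, 4 in both ORC1 lines, 14 between ORC1 and ORC2 lines, 52 in the mean of the ORC1 lines and 197 in that of the ORC2 lines. Without the filter, when more genes are tested, counts were 27 in ORC1B14, 0 in ORC1BP32 (1275 unadjusted), 22 in ORC2B2, 0 in both ORC1 lines (745), 10 in both ORC2 lines, 0 in all 4 lines (377) and 71 in the mean of the ORC2 lines, with 11 lists between ORC1 and ORC2 lines. The stricter filter gave 0 in ORC1BP32, both ORC1 lines and all 4 lines (825, 564 and 302 unadjusted) and 1 gene between the ORC1 lines.

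At an adjusted p under 0.01, a stricter limit by construction, counts were 1 in ORC1B14, 0 in ORC1BP32, 3 in ORC2B2, 19 in ORC2BP8, 0 in both ORC1 lines, 1 in both ORC2 lines, 0 in all 4 lines, 0 between ORC1 and ORC2 lines, 0 between the ORC1 lines, 6 between the ORC2 lines, 2 in the mean of the ORC1 lines and 15 in that of the ORC2 lines. For the 5 counts of 0, in this order, limma gave 1090, 684, 359, 752 and 574 genes at an unadjusted p under 0.05. Fits of only the 2 lines compared, with fewer arrays, gave 19 in ORC1BP32, 13 in ORC2B2 and 18 in ORC2BP8. With line as a random term, limma called 0 genes between ORC1 and ORC2 lines (885 unadjusted), at a correlation of -0.159 within lines. Camera with an estimated correlation called 0, 0 and 0 lists in the ORC1 lines, the ORC2 lines and between them, and fry called 2, 1 and 2. Counts of genes without the trend, with robust eBayes, with the mean over probe sets or with a 2-fold limit stayed within 1.5 times.

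Leaving out 1 array at a time gave 1 gene (without ORC1B14 replicate 1) to 77 in ORC1B14, 0 (without either ORC1BP32 array, either ORC2BP8 array or WT replicate 2) to 5 in ORC1BP32, and 7 to 42 in ORC2B2 and 14 to 156 in ORC2BP8, both lowest without WT replicate 2. It gave 0 to 5 in both ORC1 lines and 0 to 3 in all 4 lines, with 0 without ORC1B14 replicate 1, either ORC1BP32 array, either ORC2BP8 array or WT replicate 2. It gave 2 (without WT replicate 2) to 21 in both ORC2 lines, 0 (without either ORC1BP32 array) to 10 (without ORC2B2 replicate 1) between ORC1 and ORC2 lines, 0 to 5 between the ORC1 lines and 2 (without ORC2BP8 replicate 1) to 23 between the ORC2 lines. The mean of the ORC1 lines gave 0 to 36 and that of the ORC2 lines 5 to 267 (without ORC2BP8 replicate 1), both lowest without WT replicate 2. For counts of 0, limma gave at least 189 genes at an unadjusted p under 0.05. Lists numbered 6 to 8 in the ORC1 lines, 5 to 8 in the ORC2 lines and 3 (without ORC1BP32 replicate 1 or ORC2BP8 replicate 2) to 10 between them.

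The ATR and ATM list between ORC1 and ORC2 lines changed sign without ORC1B14 replicate 1, to a median of 0.0006562 (camera adjusted p = 0.526). Over all alternatives its median lay between -0.23 (without ORC1B14 replicate 2) and that value, and its adjusted p between 0.000597 and 0.751.

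With the replicate number as a block, counts were 496 in ORC1B14 (225 higher, 271 lower), 57 in ORC1BP32 (23 and 34), 251 in ORC2B2 (111 and 140), 402 in ORC2BP8 (178 and 224), 43 in both ORC1 lines, 123 in both ORC2 lines, 27 in all 4 lines, 58 between ORC1 and ORC2 lines, 11 between the ORC1 lines, 94 between the ORC2 lines, 454 in the mean of the ORC1 lines and 570 in that of the ORC2 lines. The block fit called all of the genes called without it (63 of 63 in ORC1B14, 101 of 101 in ORC2BP8) and 7, 7 and 7 lists. Deviations of same-numbered arrays from their line means correlated at 0.0812 to 0.568 (median 0.295) between lines, above 0 in 10 of 10 pairs of lines and above 0.1 in 9 of 10. With all of them above 0, each array must correlate best with an array of its own number, so that 10 of 10 did adds nothing. The rule set in advance needs each pair of lines above 0.1, so the numbers were not taken to pair the arrays. A single pair at 0.0812 does not show that the arrays are unpaired, and counts without the block ignore this structure. The correlations are a hint from the data, not from the design.

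The arrays' signal over background limits weak genes. Probe sets below the array median on 9 or more arrays were not tested, and for changes of 0.5 the test on simulated data found 8%.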

Other observations

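The search for runs of neighbouring genes, and the tests of 1 array, of a change in WT and of fewer copies, were chosen only after the results were seen. So were, for the gene lists, the tests of 1 WT array and of variation between cultures. The tests of scale, expression level and gene length were set earlier.

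In a stretch of chromosome 17, 2 keratin genes and 2 keratin-associated protein genes were called in the mean of the ORC2 lines. They were chosen after their values were seen, and no list of them was tested. The fixed list of epithelial junction and keratin genes was not called and had a median of -0.17. KRTAP2-3 rose by 3.43, KRT23 by 2.29, KRTAP3-1 by 1.72 and KRT20 by 1.31 (limma adjusted p = 0.00453, 0.0395, 0.0179 and 0.0441). The 2 lines were unequal, with KRT23 at 3.22 in ORC2B2 and 1.37 in ORC2BP8, and KRT20 at 1.99 and 0.63. The 22 tested genes of this stretch, from KRT10 to LINC00974, had median differences from WT of 0.47 in both ORC2B2 and ORC2BP8, 0.20 in ORC1B14 and 0.14 in ORC1BP32, and the stretch did not meet the rule added for runs. The call of KRTAP2-3 held without each of the 10 arrays. The calls of KRTAP3-1, KRT23 and KRT20 were lost without 2, 5 and 8 of them (highest adjusted p 0.162, 0.238 and 0.276).

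Genes of amino acid supply were looked at after their values were seen. ASNS, PSAT1 and PHGDH are members of the ATF4 list, so their values are part of its result. In the mean of the ORC1 lines ASNS fell by 1.39 (limma adjusted p = 0.0449), while PSAT1 stood at -1.05 and PHGDH at -0.73 without a call (adjusted p = 0.0766 and 0.0791). In the mean of the ORC2 lines PSAT1 stood at -0.79 and PHGDH at -0.65, again without a call (adjusted p = 0.113 and 0.0720), ASNS fell by 1.38 and the alanyl-tRNA synthetase gene AARS1 fell by 1.16 (adjusted p = 0.0268 and 0.00945). AARS1 lies in the chromosome 16 run of ORC2BP8, where it stood at -1.79, against -0.53 in ORC2B2.

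In both pairs of mutant lines against WT camera called 6 lists the same way, and 5 of them were tested further: licensing, replication, G1/S and mitosis genes, which were higher, and ATF4 genes, which were lower (the other is cholesterol synthesis; with an estimated correlation 0 lists were called, and these 5 had adjusted p between 0.30 and 0.488). Under both scalings every list median kept at least 91.3% of its size, and 0% of 10000 random lists matched on expression level lay as far out, which argues against an array-wide scale and against expression level. Without either WT array the smallest share kept was 54.3%, for the ATF4 list in the ORC1 lines without WT replicate 2, which argues, by a small margin, against 1 WT array as the whole cause. Differences between 2 arrays of a line reached 0.393 of the mutant difference for the mitosis list, and 0.627, 0.690, 0.563 and 0.734 for the licensing, replication, G1/S and ATF4 lists. Only the mitosis list passed the limit of this test, which was set after the results were seen. The labels do not say whether replicates came from separate cultures, so the test cannot decide on variation between cultures for any of these lists. For licensing, replication and G1/S replicate 2 lay above replicate 1 in each of the 5 lines. Part of the difference between 2 arrays of a line thus follows the replicate number there. An effect of the mutations, set against a single WT line, stays open and untested.

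Runs of neighbouring genes were lower in a single line each: 222 on chromosome 16 from ITFG1 to DBNDD1 in ORC2BP8 (193 below 0, median -0.38) and 45 on chromosome 5 from MOCS2 to FCHO2 in ORC1B14 (41 below 0, median -0.74). The median against the other 3 mutant lines was -0.42 and -0.77, and after removal of a trend on gene length -0.39 and -0.65, which argues against a change in WT and gene length. Against WT the medians were smaller in size for chromosome 16 (-0.26) and larger for chromosome 5 (-0.92). On the chromosome 16 run ORC1B14, ORC1BP32 and ORC2B2 stood above WT (0.10, 0.13 and 0.07). When the strongest run was sought on 1 array alone, it lay on these chromosomes for either array of ORC2BP8 and ORC1B14. It stood, on the array not used to find it, at -0.32 or lower and -0.64 or lower, which argues against 1 array. In ORC1BP32 and ORC2B2 the strongest runs of the 2 arrays lay on different chromosomes. Those found as lower, on chromosomes 17 and 18, stood at -0.16 and -0.20 on the array not used. Those found as higher, on chromosomes 19 and 4, stood at -0.036 and -0.00375 there. Fewer copies of the chromosome 16 and chromosome 5 regions may be the cause, with at least 80.6% and 91.1% of the genes below 0 on the array not used, although copy number was not analysed here and other regional causes stay open. The limit was passed by 11, 9, 9 and 5 runs in ORC1B14, ORC1BP32, ORC2B2 and ORC2BP8, of which 1, 0, 0 and 1 met the added rule, and the run of 26 genes with DSC3 in ORC2B2 narrowly missed it (-0.29 and -0.38).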
